A study of Mus musculus with 14 samples.

How the data were processed

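Total RNA of 14 tumours grown from B16-F10 mouse melanoma cells was measured on Affymetrix whole-transcript arrays of 2 designs. Per the labels, the first design held 12 tumours (4 control, 7 Res 499 and 1 Res 177) and the second design held 2 (1 control and 1 Res 177). The groups were taken from the subline given for each tumour in the labels, and the response label called both Res sublines resistant and the control sensitive. Replicate numbers were assigned in the order of the deposited samples and only name a tumour. The labels do not say whether tumours of a group came from separate mice, so p-values measure only the spread between these tumours, which may be partly technical. No 2 arrays held identical values, and correlations between arrays of the first design ran from 0.977 to 0.993.

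The deposited values are log2 expression values, 1 per probe set and tumour. The authors made them with RMA in the oligo package, per the submitters' processing notes; RMA corrects background, normalizes quantiles between arrays and summarises the probes of a set. The versions of these tools, the genome build and the probe annotation used by the authors are not given in the sources used here, and that the scale is log2 was read from the range of the values. Medians of the 12 arrays lay between 5.70 and 5.80. The 2 designs were normalized separately, so no level of one design was set against a level of the other, and no test pooled them. The arrays carry no read depth, and the number of tumours limits the precision.

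Probe sets were named from the platform annotation, and symbols were checked through Entrez numbers against the RefSeq gene table, which changed 0 symbols. Of the 41345 probe sets of the first design, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Of the 35556 probe sets of the second design, 21789 had 1 symbol, 1621 had several and 12146 had none. Only those with 1 symbol entered the tests. A gene with several probe sets was represented by the one with the highest mean, which gave 22180 genes on the first design. The 5545 genes in the lowest 25% by mean over the 12 arrays were left out and 16635 were tested. Of 9954 probe sets without exactly 1 symbol above the same level, 0 passed the threshold in Res 499 against control when tested in the same way.

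Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A fit of the 3 groups of the first design gave Res 499 against control, Res 177 against control and Res 499 against Res 177. The single Res 177 tumour in this fit is assumed to vary like the tumours of the other groups. A separate fit with 2 levels gave resistant (8 tumours) against sensitive (4 tumours). Fixed gene lists, 27 in number, were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists; 26 had the 3 tested members required, and the list of sex-linked genes did not. Beside it stand camera with a correlation estimated per list, fry, the count of members past the gene test adjusted over all genes, and the count adjusted over the list alone. For each tumour, a list's mean over its members relative to the control mean was also compared between 7 Res 499 and 4 control tumours by a two-sided exact permutation test, whose smallest possible p is 0.00606. The 2 tumours of the second design allow no test; the median difference of a list was placed among 10000 random lists of the same size matched on mean level. Genes were matched between the designs by symbol, and 15034 tested genes had a value on both.

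Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for Res 499 against control, the 12 largest rises and 12 largest falls past the threshold with non-overlapping group ranges, up to 4 called members of each list, and 11 genes whatever their values (Cd274, Ifit1, Isg15, B2m, Pmel, Tyr, Dct, Mki67, Cd8a, Cd3e and Adgre1). For the other tests it took the 6 largest changes each way past the threshold, and for the second design the 6 largest differences each way among genes above the median level. Receptor multigene families, predicted gene models, small RNAs and antigen receptor segments were left out of these picks. The exact permutation test of list means, fits without the 2 arrays of lowest weight, and covariates for the macrophage and interferon-stimulated lists were chosen after seeing the data. So were leukocyte content as a covariate outside Res 499 against control and 5 further lists (hair follicle keratins, interfollicular epidermis, sebaceous gland, MAPK pathway output and lysosome), the last also with that covariate.

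Alternatives covered the filter on dim genes, the choice of probe set, the normalization, the eBayes prior, array weights, the threshold, each array left out in turn, and leukocyte content as a covariate, taken as the mean of 5 genes (Ptprc, Cd53, Laptm5, Coro1a and Cd52). Comparisons that share the control tumours were set beside 1000 simulations of unchanged groups on the same controls and beside the 6 splits of the controls. All permutation tests were two-sided and used scipy 1.17.1 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

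The fits were tested on simulated data over 16635 genes with 200 changed genes in each of 5 runs. For Res 499 against control, 68.1% of changes of 0.5 on the log2 scale, 98.2% of changes of 1 and 99.4% of changes of 2 were recovered, and 4.94% of the calls were false. For Res 177 against control, 8.96% of changes of 0.5, 76.7% of changes of 1 and 98.5% of changes of 2 were recovered, and 5.70% of the calls were false. In 20 runs without any change 0 genes were called in all. The simulated genes varied independently and normally, with the same spread in every group. These rates thus do not cover correlated genes or groups of unequal spread. The single Res 177 tumour varied like the others by construction, so that assumption was not tested.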

Results

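The comparison addresses how tumours of melanoma cells that escaped radiation combined with CTLA4 blockade differ from tumours of sensitive cells. B16-F10 is a pigmented melanoma line of C57BL/6 mice. Per the labels, mice carried a tumour on each flank, 1 of them received 20 Gy on day 8, and mice were injected with a CTLA4-blocking antibody on days 5, 8 and 11. Cells recovered from unirradiated tumours that withstood the therapy or relapsed gave the resistant sublines Res 499 and Res 177, which were implanted again. Expression was measured in 7 Res 499, 2 Res 177 and 5 control tumours, of which 7, 1 and 4 were on the first array design. The labels do not say whether the tumours measured had themselves been treated. All levels are log2 expression values, and changes are log2 fold changes with their standard error (SE) from limma.

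In Res 499 tumours 24 genes rose and 35 fell against control tumours, out of 16635 tested. Etv5, a transcription factor induced by MAPK signalling, fell from 9.30 ± 0.18 (SD, n = 4) in control to 8.15 ± 0.24 (SD, n = 7) in Res 499, a change of -1.15 (SE 0.13, adjusted p = 0.00445). Mcoln3, an endolysosomal cation channel, rose by 0.95 (SE 0.10, adjusted p = 0.00445), and Oas1b, an interferon-induced gene of the oligoadenylate synthetase family, rose by 0.93 (SE 0.10, adjusted p = 0.00445). All 7 Res 499 tumours lay outside the range of the 4 control tumours for each of these genes. The chemokine Cxcl10, which attracts activated T cells, rose 2.51-fold (adjusted p = 0.0482), also above the controls in 7 of 7 tumours.

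Among called genes with non-overlapping ranges that the naming rule admits, the largest rise was that of Phyhipl, at 1.85 (SE 0.31, adjusted p = 0.0379), from 5.93 ± 0.44 (SD, n = 4) to 7.78 ± 0.64 (SD, n = 7). It was followed by Gxylt2, a xylosyltransferase acting on Notch, at 1.37 (SE 0.23), Cxcl10 at 1.33 (SE 0.25) and Plau, the urokinase plasminogen activator, at 1.04 (SE 0.19). Car8 rose by 0.98, the junction protein gene F11r by 0.95, the cytokine receptor Lifr by 0.92, the histone gene H2ac15 by 0.92, the kinase Prkcq by 0.90 and the interferon-induced Ifi27 by 0.81. H2ac15 belongs to a family of near-identical histone genes that share probe sequence, so its value is uncertain. The largest fall was that of Cfap46, a ciliary protein gene, at -1.32 (SE 0.19, adjusted p = 0.0176). Lgi4 fell by 1.07, the semaphorin Sema6a by 0.89, Cdhr4 by 0.88, the mismatch repair gene Mlh3 by 0.88, Ehd3 by 0.87, the glypican Gpc6 by 0.84, the potassium channel Kcnn4 by 0.83, Usp2 by 0.83, the phosphatidate phosphatase Lpin1 by 0.81 and Mtss2 by 0.81. Adjusted p-values of these 24 genes lay between 0.00445 and 0.0482. Over 22 alternatives the change of Phyhipl ran from 0.92 to 2.36 and that of Etv5 from -1.23 to -0.63. Both kept their direction, but the sizes of these changes depended on the alternative.

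**Figure D1:**
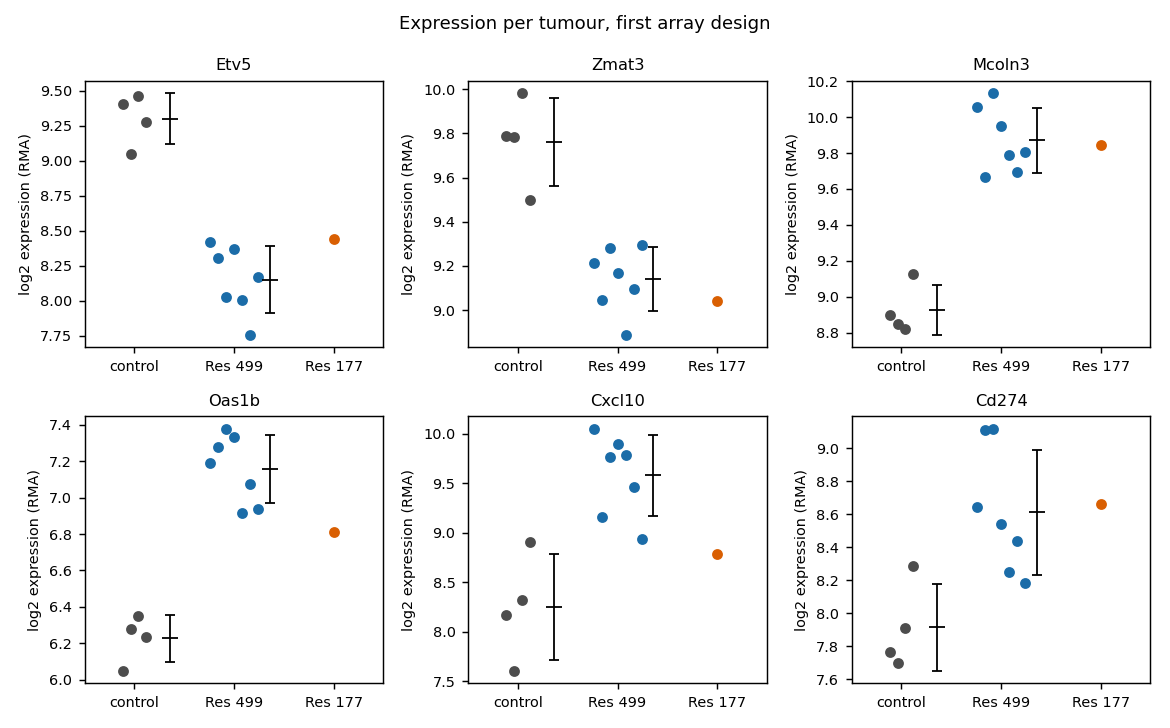
Expression of 6 genes in each tumour of the first array design, on the log2 scale of RMA values. Points are tumours (4 control, 7 Res 499, 1 Res 177), and bars give the mean and SD of control and Res 499. Res 499 tumours lie below all controls for Etv5 and Zmat3 and above all controls for Mcoln3, Oas1b and Cxcl10, while for Cd274 5 of 7 do.

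Across the genome, 2159 genes had an unadjusted p under 0.05 where 832 are expected by chance, and 397 genes (2.39%) had non-overlapping ranges, where chance gives 0.606%. Of the 59 called genes, 58 had non-overlapping ranges, and Lpar4 did not. The count depended on single tumours: it ranged from 6 without control replicate 4 to 196 without Res 499 replicate 2, and 6 genes (Car8, Cdhr4, Etv5, Lgi4, Mcoln3 and Oas1b) were called in every one of the 11 fits that left out 1 tumour. It was 11 and 22 without control replicates 2 and 3, 24, 14, 18, 23 and 37 without Res 499 replicates 1, 3, 4, 6 and 7, and 27 with leukocyte content as a covariate.

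Interferon-stimulated genes, which encode antiviral effectors and their regulators, lay higher in Res 499 as a group: 26 of 28 tested members had positive changes, with a median of 0.71, which was 0.24 with leukocyte content as a covariate. No single member passed the test over all genes, while 17 rose when adjusted over the list alone, among them Rtp4 at 1.40, Usp18 at 1.25 and Irf7 at 0.83. Camera with the preset correlation gave the list an adjusted p of 1.88e-13, and it gave an adjusted p = 0.430 with an estimated correlation. The list means per tumour spread widely in Res 499, from -0.02 to 1.30 relative to the control mean, against -0.13 to 0.15 in control tumours. In all, 5 of 7 Res 499 tumours lay above every control (exact permutation p = 0.0424, adjusted p = 0.229 over 26 lists). Ifit1 differed by 0.69 (SE 0.37, adjusted p = 0.461) and Isg15 by 0.25 (SE 0.19, adjusted p = 0.628). Macrophage and monocyte markers also lay higher as a group: all 18 had positive changes, with a median of 0.85 and tumour means from -0.29 to 1.78 in Res 499. The lists did not follow each other in every tumour: replicate 4 had 0.89 for the interferon-stimulated and 0.26 for the macrophage list, and replicate 5 had 0.56 and 1.62. None of the 18 passed the gene test over all genes or adjusted over the list alone. Their camera adjusted p was 2.16e-07 at the preset correlation and adjusted p = 0.430 with an estimated correlation, and 4 of 7 tumours lay above every control (exact permutation p = 0.109, adjusted p = 0.236 over 26 lists). Adgre1, the macrophage surface protein F4/80, was at 8.14 ± 1.44 (SD, n = 7) against 6.72 ± 0.38 (SD, n = 4) in control (adjusted p = 0.370). Xist, an RNA made by female cells, differed by 0.55 (SE 0.43, adjusted p = 0.641).

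Genes of antigen presentation and checkpoint control lay in the same direction. Of 15 MHC class I genes 14 had positive changes (median 0.43), of 8 MHC class II genes 8 (median 0.57), of 20 checkpoint ligands 16 (median 0.14) and of 13 T cell checkpoint receptors 11 (median 0.20). None of these members passed the gene test over all genes, and none did adjusted over the list alone. Camera adjusted p-values were 0.00235, 0.00636, 0.0261 and 0.00242, and adjusted p = 0.437, 0.430, 0.437 and 0.430 with an estimated correlation. Cd274, which encodes the checkpoint ligand PD-L1, was at 8.61 ± 0.38 (SD, n = 7) against 7.92 ± 0.26 (SD, n = 4), a difference of 0.70 (SE 0.19) that did not pass the threshold (adjusted p = 0.138). B2m, the light chain of MHC class I, differed by 0.10 (SE 0.10, adjusted p = 0.749). Of 20 chemokine genes 19 had positive changes (median 0.38). Cxcl10 rose over all genes and 4 rose adjusted over the list alone, among them Ccl3 at 1.22 and Ccl7 at 1.26 (camera adjusted p = 2.27e-05, and adjusted p = 0.430 with an estimated correlation). The macrophage marker median beside all of these lists was 0.85, and with leukocyte content as a covariate the MHC class I, MHC class II and checkpoint ligand medians turned to -0.069, -0.079 and -0.0079.

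Medians of further immune and inflammatory lists were 0.17 for CD8 and NK cytotoxic markers (11 of 11 positive), 0.21 for dendritic cell markers (9 of 10), 0.22 for NF-kappaB and inflammatory cytokine genes (11 of 15) and 0.12 for interferon receptors, kinases and nucleic acid sensors (14 of 16). Their camera adjusted p-values were 0.0144, 0.00805, 0.0496 and 0.00765, and adjusted p = 0.448, 0.430, 0.437 and 0.430 with an estimated correlation. T cell markers had a median of 0.12 (camera adjusted p = 0.0786), B cell markers 0.12 (0.0743) and neutrophil markers 0.11 (0.0593), and these lists did not pass the test. Cd8a differed by 0.20 (SE 0.17, adjusted p = 0.678) and Cd3e, a subunit of the T cell receptor complex, by 0.33 (SE 0.21, adjusted p = 0.561). No member of these lists passed the gene test over all genes or adjusted over the list alone. The macrophage marker median in the same tumours was 0.85, and with leukocyte content as a covariate the CD8 and NK and T cell medians turned to -0.052 and -0.051, Cd8a to -0.056 and Cd3e to -0.052.

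Target genes of p53 lay lower in every Res 499 tumour. Of 16 tested members 12 had negative changes, with a median of -0.27. Zmat3, a p53-induced RNA-binding protein gene, fell from 9.76 ± 0.20 (SD, n = 4) to 9.14 ± 0.14 (SD, n = 7), a change of -0.62 (SE 0.10, adjusted p = 0.0323). It was the only member that passed over all genes, and 7 fell adjusted over the list alone, among them the cell cycle inhibitor Cdkn1a at -0.71, Ccng1 at -0.49 and Trp53inp1 at -0.86. The list mean was -0.32 ± 0.06 (SD, n = 7) in Res 499 against 0.00 ± 0.14 (SD, n = 4), and 7 of 7 tumours lay below every control. The exact permutation p was 0.00606, the smallest it can give, and 0.158 adjusted over 26 lists. Camera gave an adjusted p of 1.21e-06 at the preset correlation and an adjusted p = 0.285 with an estimated correlation, and fry gave 0.0267.

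Of the melanocyte lineage and pigmentation genes, 13 of 17 had positive changes with a median of 0.10 (camera adjusted p = 0.0167, and adjusted p = 0.437 with an estimated correlation). None passed over all genes; 4 rose and Sox10 fell, at -0.26, adjusted over the list alone. The pigment genes Pmel, Tyr and Dct differed by 0.16 (SE 0.06), -0.05 (SE 0.17) and -0.04 (SE 0.07). Unfolded protein response genes had a median of 0.14 (12 of 14 positive, camera adjusted p = 0.00198, and adjusted p = 0.430 with an estimated correlation), and 1, Sdf2l1, rose adjusted over the list alone against 0 over all genes. Oxidative phosphorylation genes had a median of 0.09 (18 of 20 positive, camera adjusted p = 0.00236, and adjusted p = 0.437 with an estimated correlation), and skeletal muscle markers of -0.17 (1 of 10 positive, camera adjusted p = 0.0169, and adjusted p = 0.448 with an estimated correlation). The skeletal muscle shift rested on control replicate 2, whose list mean was 0.45 against -0.22 to -0.05 in the other controls, and without it the median was -0.03 (camera adjusted p = 0.785). The remaining lists did not pass: cell cycle genes had a median of 0.01 (camera adjusted p = 0.386), hypoxia and glycolysis genes -0.13 (0.111), dedifferentiation and mesenchymal genes 0.03 (0.505), endothelial markers 0.15 (0.151), fibroblast and matrix markers 0.11 (0.205), adipocyte markers 0.27 (0.0935) and keratinocyte markers 0.01 (0.805). With leukocyte content as a covariate the hypoxia, dedifferentiation, endothelial, fibroblast and adipocyte medians turned to 0.017, -0.095, -0.14, -0.40 and -0.070. Of these only the fibroblast list then passed camera at the preset correlation (adjusted p = 3.37e-05). The proliferation gene Mki67 differed by -0.09 (SE 0.12, adjusted p = 0.824). In these 9 lists other than the melanocyte and unfolded protein response lists, 0 members passed over all genes and 0 adjusted over the list alone.

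**Figure D2:**
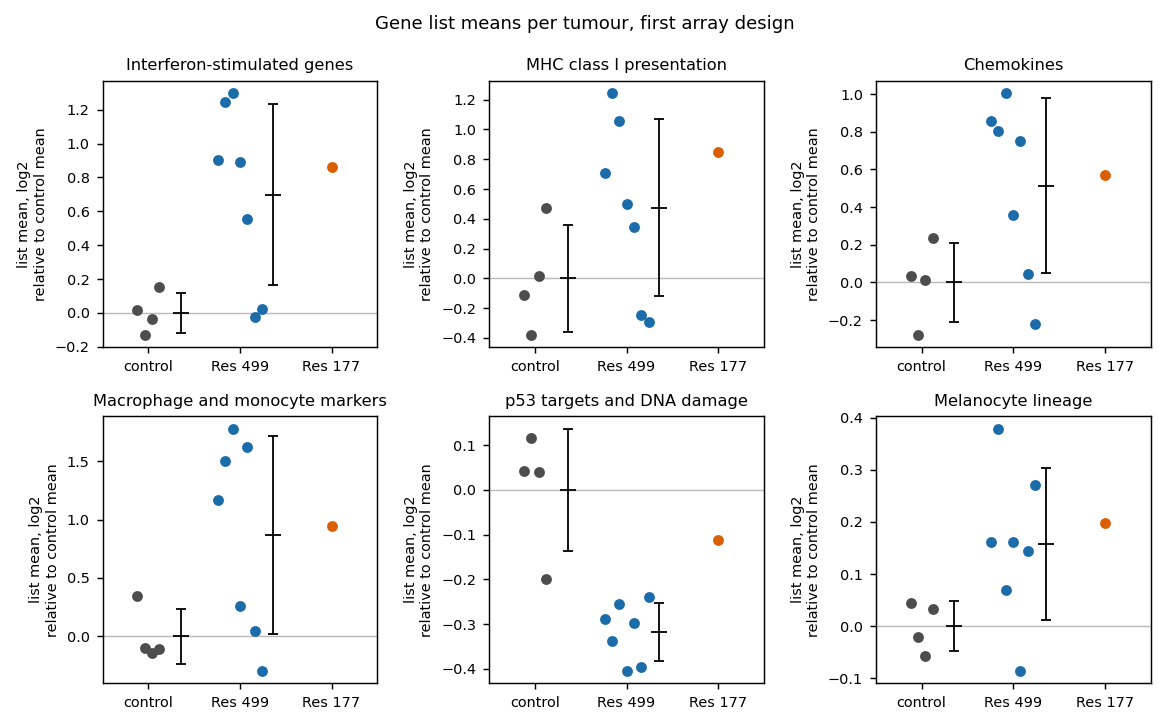
Mean of 6 gene lists in each tumour of the first array design, in log2 units relative to the mean of the control tumours. Points are tumours (4 control, 7 Res 499, 1 Res 177), and bars give the mean and SD of control and Res 499. Interferon-stimulated list means run from -0.02 to 1.30 in Res 499 and macrophage list means from -0.29 to 1.78, while p53 target list means lie between -0.40 and -0.24, below all controls.

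At the preset correlation camera thus called 16 of 26 lists in Res 499, 14 higher and 2 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.285; 1 list had an unadjusted p under 0.05), fry called 1 and the exact permutation test 0 (4 lists had an unadjusted p under 0.05). The count of 16 was 8 without Res 499 replicate 2, 10 with the lowest 50% of genes left out and 6 with leukocyte content as a covariate.

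When both sublines were pooled by the response label, 48 genes rose and 54 fell in resistant against sensitive tumours. Of the 102 genes, 52 were among the 59 called in Res 499. Since 7 of the 8 resistant tumours were Res 499, these p-values measure spread between tumours, mostly within Res 499, and not between resistant sublines. Rtp4, an interferon-induced chaperone gene, rose by 1.42 (SE 0.25, adjusted p = 0.0324), Plxnc1, a semaphorin receptor, by 1.28 (SE 0.24, adjusted p = 0.0336) and Mgll, the monoacylglycerol lipase, by 1.27 (SE 0.24, adjusted p = 0.0395). Phyhipl rose by 1.71, Gxylt2 by 1.37 and the lysophosphatidic acid receptor Lpar4 by 1.24. Cfap46 fell by 1.30, Odf3l1 by 1.17, Etv5 by 1.11, Lgi4 by 1.05, the nuclear envelope gene Syne1 by 1.02 and Tmem59l by 1.01. Cd274 differed by 0.70 (SE 0.18, adjusted p = 0.101) and passed only when adjusted over the list alone. Of the unfolded protein response genes Sdf2l1 rose by 0.50 over all genes, and of the chemokines 0 rose over all genes and 4 adjusted over the list alone. Camera called 17 of 26 lists, 15 higher and 2 lower (p53 targets, and skeletal muscle markers, which lay high in control replicate 2), and 0 with an estimated correlation (smallest adjusted p = 0.221; 1 list had an unadjusted p under 0.05). The interferon-stimulated list had a median of 0.74 with 1 member called over all genes and 19 adjusted over the list alone (adjusted p = 0.371 with an estimated correlation), and macrophage markers had a median of 0.92. The p53 list had a median of -0.27 with 2 members that fell over all genes and 7 adjusted over the list alone (adjusted p = 0.221 with an estimated correlation). The gene count ranged from 9 without control replicate 4 to 141 without Res 499 replicate 2. It was 12, 37, 42, 35, 41, 58, 42 and 59 without control replicates 2 and 3, Res 499 replicates 1, 3, 4, 6 and 7, and the Res 177 tumour. With the sublines weighted equally the gene count was 42 (35 higher and 7 lower), of which only 15 were among the 102. Of the 12 genes named for the size of their change, 3 (Cfap46, Etv5 and Lgi4) stayed past the threshold. With leukocyte content as a covariate the gene count was 41, of which 26 were among the 102, and 4 of the 12 named genes stayed.

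In the single Res 177 tumour of the first design, keratin and desmosome genes stood far above every other tumour. With 1 tumour in this arm the SE and p come from the spread of the other groups, and the test cannot separate the subline from the tumour. Krt17 rose by 3.59 (SE 0.23, adjusted p = 2.31e-06), Krt71 by 3.29 (SE 0.19, adjusted p = 1.08e-06), Krt25 by 3.21 (SE 0.14, adjusted p = 8.48e-08) and the desmosomal genes Dsc3 by 3.25, Perp by 3.01 and Dsp by 2.91. Krt25 and Krt71 are keratins of the inner root sheath of the hair follicle. Of 9 keratinocyte markers 6 rose over all genes and 8 adjusted over the list alone, with a median of 1.22, and the list passed with an estimated correlation (adjusted p = 5.17e-04). In all, 35 genes rose and 0 fell by limma, and 679 had an unadjusted p under 0.05 where 832 are expected. The count was 2 with the lowest 50% of genes left out and 101 with no filter on dim genes.

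The interferon-stimulated list had a median of 0.91 in this tumour (28 of 28 positive), MHC class I genes 0.92, MHC class II genes 0.92, T cell checkpoint receptors 0.36, macrophage markers 0.97, chemokines 0.27, p53 targets -0.26 and hypoxia and glycolysis genes -0.20. Each of these 8 lists passed camera at the preset correlation, with an adjusted p = 0.602 with an estimated correlation for each. Over all genes and adjusted over the list alone, 0 members of these lists passed except in the p53 list. There Perp rose, a gene that is also in the keratinocyte list, and 2 genes fell adjusted over the list alone, Cdkn1a and Zmat3. Against Res 177, 0 genes were higher and 39 lower in Res 499 by limma (488 had an unadjusted p under 0.05), led by Krt17 at -3.47, Krt71 at -3.37, Krt25 at -3.18, Dsc3 at -3.17, Dsp at -2.90 and Perp at -2.87. Of the 35 genes that rose in Res 177, 33 were among these 39, and the 39 became 2 with the lowest 50% of genes left out and 113 with no filter. The keratinocyte list was the only one of 26 called between the Res 499 tumours and this single Res 177 tumour, with a median of -1.26, 5 members lower over all genes and 8 adjusted over the list alone (adjusted p = 2.26e-04 with an estimated correlation).

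**Figure D3:**
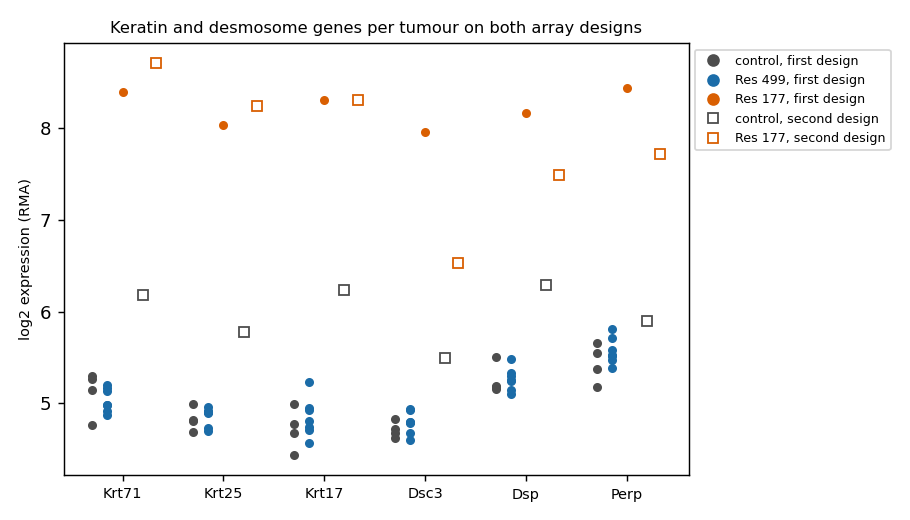
Expression of 6 keratin and desmosome genes in each tumour, on the log2 scale of RMA values. Filled circles are tumours of the first array design and open squares the 2 tumours of the second, whose levels are normalized separately and compare only with each other. The Res 177 tumour lies above the control tumours on each design, by 3.29 for Krt71 on the first and 2.53 on the second.

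The second design gave another Res 177 tumour with a control tumour of its own, without replicates. Of the 59 genes changed in Res 499, 58 had a value there, and 57 (98.3%, exact 95% interval 90.8% to 100.0%) differed from control in the same direction in Res 177. The share was 59.9% among the 14976 other genes, and genes are not independent replicates. The exception, Gm5784 (-0.44 in Res 499 and 0.16 there), was named after its values were seen. Cxcl10 was higher by 2.27, Plau by 1.74, Gxylt2 by 1.74, Mcoln3 by 1.21 and Prkcq by 1.20. Cfap46 was lower at -1.94, Lgi4 at -1.43, Zmat3 at -1.17 and Etv5 at -1.0, while Mlh3 differed by -0.06, F11r by 0.10 and H2ac15 by 0.03. Cd274 was higher by 1.16.

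**Figure D4:**
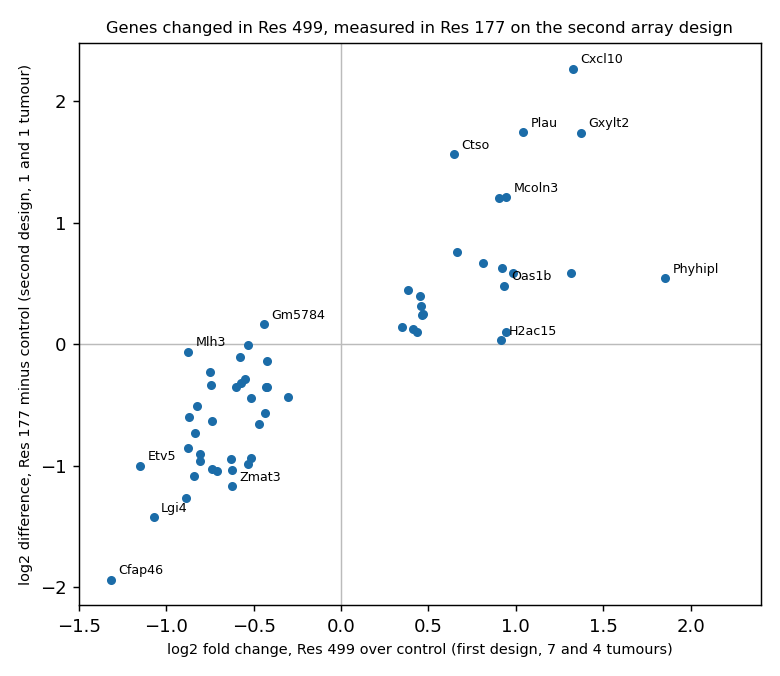
Each point is 1 of the 58 genes changed in Res 499 that have a value on both array designs. The horizontal axis is the log2 fold change of Res 499 over control on the first design, and the vertical axis the log2 difference between the Res 177 and the control tumour of the second design. In 57 of 58 genes both have the same sign.

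The largest differences on the second design were those of the hair keratin-associated genes Krtap7-1 (4.42) and Krtap8-1 (3.28), the MHC class II gene H2-Aa (3.92), Dapl1 (3.49), the immunoproteasome gene Psmb8 (3.15) and the interferon-inducible GTPase Iigp1 (3.11). The lowest were Ifnz (-2.0), Slc12a2 (-1.95), Cfap46 (-1.94), Azgp1 (-1.90), Scrg1 (-1.83) and Hes1 (-1.73). Interferon-stimulated genes had a median difference of 0.73, MHC class I genes 0.86, MHC class II genes 1.87, macrophage markers 0.80 and keratinocyte markers 0.58, each at percentile 100 of 10000 matched random lists. Checkpoint ligands (0.25, percentile 99.9) and chemokines (0.25, percentile 100.0) were also high, as were T cell checkpoint receptors (0.14, percentile 98.7) and skeletal muscle markers (0.20, percentile 99.6). The p53 targets had a median of -0.35, at percentile 0, and low medians were also those of adipocyte markers (-0.23, percentile 0.03), hypoxia and glycolysis genes (-0.12, percentile 0.10) and endothelial markers (-0.16, percentile 0.61). Skeletal muscle and adipocyte markers thus had the opposite sign to the Res 177 tumour of the first design, at -0.09 and 0.22, so host tissue markers differed within this single pair. Cell cycle genes had a median of 0.25 at percentile 100 on this design, against 0.04 in the Res 177 tumour of the first.

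Across 16635 genes, the changes of Res 499 and of Res 177 on the first design correlated at r = 0.657 (Spearman 0.563), but both use the same 4 control tumours. Unchanged groups simulated on these controls gave a median r of 0.375 and a range of -0.480 to 0.866 that covers 95% of 1000 simulations. The covariance was 0.0358 against a simulated median of 0.0105, and it lay inside the range of -0.0122 to 0.0467 that covers 95% of simulations. With the controls split between the contrasts r was 0.427 on average (0.354 to 0.478 over 6 splits), and against the Res 177 tumour of the second design it was 0.524. Of the 59 genes called in Res 499, 58 had the same sign in the first Res 177 tumour, where the controls are shared. The exception was Apobec2, also named after its values were seen, at -0.47 in Res 499 and 0.0025 in Res 177. The lists of genes called in Res 499 and in Res 177 shared 0 genes, where independent lists would share 0.0505.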

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

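The tests of the interferon-stimulated list, of skin tissue and of dilution were chosen only after the result was seen, and the tests of sample splits, sebaceous gland tissue, leukocyte content of the called genes and passage were chosen before. Some tumours lay far from the rest of their group. Control replicate 3 had Phyhipl at 5.27 against 6.10 to 6.21 in the other controls. Control replicate 2 had Adgre1 at 7.28 and a macrophage and monocyte list mean of 0.35, above 6.57 and -0.10 in the nearest control. Control replicate 5 had Odf3l1 at 8.54 and Dsp at 5.50. Res 499 replicate 5 had Plxnc1 at 9.09 and an adipocyte list mean of 1.68, where the other Res 499 tumours reached 0.30 at most. Res 499 replicate 2 had Lpar4 at 7.26. These are 8 of 168 groups of values, where chance alone gives about 8.4.

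Res 499 tumours differed from the single Res 177 tumour of the first design, by a limma test that cannot separate subline from tumour, in keratin and desmosome genes: Krt17 (-3.47), Krt71 (-3.37), Krt25 (-3.18), Dsc3 (-3.17), Dsp (-2.90) and Perp (-2.87), and the keratinocyte list (-1.26). The same genes were higher in the Res 177 tumour of the second design, by 2.08 for Krt17, 2.53 for Krt71 and 2.47 for Krt25, so the pattern was seen in both Res 177 tumours. Skin and hair follicle tissue taken with the tumour is a candidate explanation: the lowest percentile of epidermis and hair follicle list medians among matched random lists was 99.2 over both tumours. That lowest value belongs to the epidermis list on the second design, whose median difference was only 0.12, against 0.68 on the first. Hair follicle medians were 1.21 on the first design and 0.99 on the second. Against the control tumours Krt14 was higher by 2.39 and Krt10 by 2.35 on the first design and by 1.08 and 0.35 on the second, and the lists hold Krt25, Krt71 and Dsp, which are part of the pattern. Sebaceous gland genes reached percentile 99.9 in the first tumour and 80.4 in the second, which leaves them open, and keratin expression by the Res 177 tumour cells was not tested.

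As a list, interferon-stimulated genes were high in some Res 499 tumours and near control in others, with list means from -0.02 to 1.30. Single genes differed from this. Oas1b, Ifi27 and the list member Rtp4 lay above every control in 7 of 7 Res 499 tumours. In replicates 6 and 7 Ifit1 lay within the control range and Isg15 below it. With leukocyte content as a covariate the median change of the list went from 0.71 to 0.24. The median SE of the members was 0.20, and camera with an estimated correlation gave a p of 0.386. After that adjustment 5 of 7 Res 499 tumours lay above the highest control, at 0.12, with an exact permutation p of 0.158. They were not the same 5: replicate 5 was above every control only before the adjustment and replicate 7 only after it. The adjusted means of replicates 5 and 7 were -0.16 and 0.23. For the list, host leukocytes and an interferon response of the tumour cells therefore cannot be told apart with 7 and 4 tumours, and both could contribute. Leukocyte genes can also be part of an interferon response, so the adjustment may remove some of it.

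The genes changed in Res 499 had the same sign in the second-design Res 177 tumour in 57 of 58 cases. A difference in host leukocytes stays open for that Res 177 tumour. With leukocyte content as a covariate 59 of 59 genes kept their direction and the median size of change stayed at 88.8% of its value. The median SE went from 0.11 to 0.14 and 17 genes stayed past the threshold. The calling rule favours this outcome: 58 of the 59 genes had non-overlapping ranges, while leukocyte content ran from -0.39 to 1.71 relative to control in Res 499. Genes that follow leukocytes were thus unlikely to be called. Res 499 replicates 6 and 7 had leukocyte content of 0.20 and -0.39, against -0.16 to 0.23 in control. They still lay outside the control range for the 58 genes with non-overlapping ranges. These values argue against leukocyte content as the source of the Res 499 changes of those 58 genes. The covariate fit also held no tumour of the second design, so it cannot decide the question there. Dilution of tumour RNA by host RNA would lower melanocyte genes too, but the melanocyte list median was 0.10 while that of the p53 list was -0.27. The melanocyte shift was small (exact permutation p = 0.0727, adjusted p = 0.229 over 26 lists), and 4 of its 17 genes were negative. The melanocyte list alone therefore does not exclude dilution as the cause of the lower p53 target genes. In Res 499 replicates 6 and 7, whose leukocyte content lay within or below the control range, p53 list means were -0.40 and -0.24, below every control. These values argue against dilution by leukocyte RNA as the cause in these tumours. Dilution by other host RNA is not excluded. Passage through a treated mouse or clonal origin stays open, because 0 sensitive sublines isolated from treated mice were among the groups. A change tied to resistance remains a hypothesis.

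For the 59 genes of Res 499 against control, 1 of 100 drawn splits of the 11 tumours, the real one, called as many. The highest other split called 2, so a count of this size was rare among random splits. This concerns the count and no single gene. It also cannot separate the subline from technical or mouse effects shared within a group. For the 102 genes of resistant against sensitive, 3 of 100 splits of the 12 tumours called as many, the real one included. The highest other split called 283 genes by setting Res 177 replicate 2 and Res 499 replicates 1, 2 and 3 against the rest. The next called 130 by setting apart Res 177 replicate 2 and Res 499 replicates 2, 3 and 5. Tumours set apart in these splits had leukocyte content of 1.02 to 1.71 relative to control, against -0.39 to 0.29 in Res 499 replicates 4, 6 and 7. Leukocyte-rich Res 499 replicates 5 and 1 each stayed with the rest in 1 of the splits. The resistant tumours thus hold a structure that largely goes with leukocyte content. For the 16 gene lists of Res 499, 24 of 100 splits called as many and the highest other called 22, so chance cannot be excluded for the number of lists called at the preset correlation.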

How the results depend on the processing

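The tests without the 2 arrays of lowest weight, with a macrophage or interferon-stimulated covariate and by exact permutation of list means, and the leukocyte covariate for resistant against sensitive, were chosen only after the result was seen. Against the 59 genes of Res 499 and the 102 of resistant against sensitive, the counts were 39 and 64 with each array centred on its median, 356 and 330 with array weights, 229 and 254 at a threshold of 0.10, 9 and 16 with a log2 change of at least 1, and 27 and 41 with leukocyte content as a covariate. Leaving out the 2 arrays of lowest weight (Res 499 replicates 5 and 2) gave 182 and 168. Res 499 gave 28 genes with the macrophage covariate and 14 with the interferon-stimulated covariate. Weighting the sublines equally gave 42 for resistant against sensitive, 15 of them among the 102. The counts stayed within 1.5 times with no filter (47 and 72), the lowest 50% left out (84 and 115), means over probe sets (64 and 100), another quantile normalization (74 and 89) and an intensity trend (78 and 96). Array weights kept 59 of the 59 genes, the leukocyte covariate 17 and the interferon-stimulated covariate 8. Of the 102 genes the leukocyte covariate kept 26. Of the named genes past the threshold, 1 of 25 in Res 499 and 1 of 12 in resistant against sensitive, Etv5 in both, and 0 of 6 in each comparison with Res 177 passed in every alternative, and 0 turned direction. A gene left out by the filter of an alternative counts here as not passed. So does a gene with a smaller change in the alternative that asks for a log2 change of at least 1. In Res 499 this removes Car8, Mcoln3, Oas1b and Cdhr4. Per gene, 22 alternatives were counted without that one and without the macrophage and interferon-stimulated covariates. Car8, Mcoln3, Oas1b and Cdhr4 passed in all 22, and Lgi4 in the 21 that held it. Sizes varied more than directions. In resistant against sensitive, Phyhipl ran from 0.85 to 2.25 and Etv5 from -1.20 to -0.61 over 23 alternatives.

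The 35 genes of Res 177 against control and 39 of Res 499 against Res 177 became 101 and 113 with no filter on dim genes and 2 and 2 with the lowest 50% left out, since the filter by mean level sets which genes are tested. The 16 lists became 10 with the lowest 50% left out, 6 with the leukocyte covariate, 9 without the 2 arrays of lowest weight, 0 with an estimated correlation, 1 by fry and 0 by exact permutation. The agreement of Res 499 and Res 177 changes was 0.427 with the controls split and 0.524 with the second design, which do not share controls.

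With 1 tumour left out, counts ranged from 6 (without control replicate 4) to 196 (without Res 499 replicate 2) for Res 499, 9 to 141 for resistant against sensitive with the same tumours, 31 to 37 for Res 177, 32 to 42 for Res 499 against Res 177, and 8 (without Res 499 replicate 2) to 20 for the lists. Directions turned for values near 0: Tyr ran from -0.13 to 0.044, the keratinocyte list from -0.022 to 0.039 and the cell cycle list from -0.036 to 0.056. The adipocyte list ran from 0.0095 to 0.34, where the direction of camera turned and not the median.

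With leukocyte content as a covariate these changes turned: Isg15 -0.095, B2m -0.069, Tyr 0.017, Cd8a -0.056, Cd3e -0.052, Adgre1 -0.076, and the lists of MHC class I (-0.069), MHC class II (-0.079), checkpoint ligands (-0.0079), T cells (-0.051), CD8 and NK cells (-0.052), macrophages (0.015), endothelium (-0.14), fibroblasts (-0.40), adipocytes (-0.070), dedifferentiation (-0.095), hypoxia (0.017) and NF-kappaB (0.0054). In the macrophage and NF-kappaB lists the direction of camera turned and the median stayed above 0. Of these only the fibroblast list passed the test (adjusted p = 3.37e-05, range over its alternatives 3.37e-05 to 0.741). The adipocyte list was at -0.042 without the 2 arrays of lowest weight. The cause was not tested for these. No paired analysis was possible because the labels give no replicate numbers. Dim genes lie near background on these arrays, so small changes in them are not resolved.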

Other observations

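The relations between lists across tumours, the MAPK test and the leukocyte covariate for the lysosome list were chosen only after the result was seen, while the lysosome permutation test was chosen before its result. Over the 7 Res 499 tumours the interferon-stimulated list moved with MHC class I genes (Pearson r = 0.982, exact permutation p = 0.00238, adjusted p = 0.0238 over 10 relations, Spearman 0.929, permutation p = 0.00675). It did so with T cell markers (r = 0.895, exact permutation p = 0.00556, adjusted p = 0.0278, Spearman 0.893, permutation p = 0.0123) and with Cd274 (r = 0.851, exact permutation p = 0.0115, adjusted p = 0.0384, Spearman 0.893, permutation p = 0.0123). Each relation was also taken without the 2 tumours farthest from the median of 1 of its 2 measures, so the pair left out differed. For MHC class I genes, Cd274 and macrophage markers it was Res 499 replicates 6 and 7, and for T cell markers replicates 2 and 3. Without them r was 0.940 for MHC class I genes, 0.795 for T cell markers and 0.991 for Cd274. The T cell relation thus kept replicates 6 and 7. With macrophage markers r was 0.776 (exact permutation p = 0.0651, adjusted p = 0.0930, Spearman 0.750, permutation p = 0.0663) and 0.242 without replicates 6 and 7, so that relation rests on them. With the leukocyte covariate genes r was 0.812 (exact permutation p = 0.0444, adjusted p = 0.0741, Spearman 0.857, permutation p = 0.0238, adjusted p = 0.0476) and 0.414 without 2 tumours. With chemokines r was 0.867 (exact permutation p = 0.0258, adjusted p = 0.0516, Spearman 0.893, permutation p = 0.0123) and 0.418, and with Xist 0.708 (exact permutation p = 0.0829, adjusted p = 0.104, Spearman 0.786, permutation p = 0.0480) and 0.911. With the p53 list r was 0.0742 (exact permutation p = 0.864, Spearman 0.179, permutation p = 0.713) and 0.166 without 2 tumours. Xist and the macrophage list had r = 0.876 (exact permutation p = 0.0246, adjusted p = 0.0516, Spearman 0.786, permutation p = 0.0480) and 0.730 without 2 tumours, and macrophage markers and the p53 list 0.278 (exact permutation p = 0.515, Spearman 0.107, permutation p = 0.840) and 0.853. With 7 tumours several of these values thus hang on 2 of them, which are not the same 2 in every relation.

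Genes that respond to MAPK signalling may be lower in the resistant sublines, as Etv5 is. In Res 499 Spry4 differed by -0.56 and Etv4 by -0.35, neither past the threshold, and in the second-design Res 177 tumour by -1.11 and -0.65. Members of the list also went the other way: 3 of 10 were positive in Res 499, with Epha4 at 0.48 and Phlda1 at 0.19, and 4 of 10 in the second-design Res 177 tumour, where these were at 0.23 and 0.29. The list of 10 genes had an exact permutation p of 0.0303 with Etv5. Without Etv5, which had been seen, the exact permutation p was 0.152 in Res 499, and the list median lay at percentile 0.04 of matched random lists in the second-design Res 177 tumour. The test first counted a p over 0.05 as excluding the hypothesis; this bound was replaced after the result was seen, because a p that misses the threshold excludes nothing. The hypothesis stays open.

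Lysosome genes may be higher in Res 499. The list was made after its members Atp6v0b and Ctsd had been seen among the called genes, so it was tested without them: its mean was above every control in 6 of 7 tumours (exact permutation p = 0.0182). Macrophage markers, whose cells are rich in lysosomes, lay higher in the same tumours, with a median of 0.85 (18 of 18 positive). With leukocyte content as a covariate the lysosome median went from 0.17 to 0.12, and without the called members from 0.15 to 0.090 (median SE of the members 0.11), so host macrophages stay open as a source. The V-ATPase subunit Atp6v0b rose by 0.47 (SE 0.06, limma adjusted p = 0.0126). In Res 177 the list without called members lay at percentile 98.5 on the first design and 72.6 on the second, which leaves a change shared by both sublines open.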
